A study of Mus musculus with 6 samples.

How the data were processed

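RNA was sequenced from 6 samples of mouse biliary epithelial cells, 3 labelled as competent for primary cilia and 3 as depleted of them. Per the labels' protocols, bile ducts were picked by hand from enzyme-digested liver, passaged 4 to 5 times as organoids in gel and plated on collagen. Also per the labels' protocols, poly-A RNA was selected and libraries were made with a directional NEBNext Ultra II kit. Per the submitters' processing notes, the tools were FastQC 0.11.9, MultiQC 1.3, cutadapt 1.16, STAR 2.7.1a, featureCounts and DESeq2 1.34.0, with the mouse genome GRCm38. The role and order of these tools, the version of featureCounts, the gene annotation and the strand setting of the counting were not given in the sources used here. The values deposited by the authors were raw counts per gene, whole numbers that were not normalized, in a single table with a column per sample. Columns were matched to samples by the group and replicate number in their names, with the columns named WT taken as cilia competent and those named KO as cilia depleted. The table held 32061 genes, of which 11507 had no count in any sample, and 0 columns belonged to other samples. Of the gene identifiers, 32009 were found in GENCODE M21, an annotation of GRCm38, from which coordinates, strand, transcript lengths and GC content were taken; 31976 had a symbol in the name table used. Some genes of the lists, such as Tctn2, were not analysed here.

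Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, libraries were scaled by TMM, and the groups were compared with the quasi-likelihood F-test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Every adjusted p of a gene comes from this test unless another tool is named. All 6 samples entered the fit with the group as the only term. Fold changes are depleted over competent, standard errors are on the log2 scale, and CPM values are scaled by TMM. TMM factors were 1.04 to 1.06 in competent and 0.954 to 0.960 in depleted samples. The common biological coefficient of variation was 5.20%.

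Before the data were examined, 30 gene lists were fixed, covering cilium machinery, cilium-dependent signalling, senescence, cell cycle, injury responses, markers of biliary and other liver cells, and responses that 4OHT can give by itself. Lists with at least 3 tested members, the sex-linked check excepted, were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and fry were run as alternatives. The rule for named genes was also fixed beforehand. It took Wdr35, the 12 largest rises and the 12 largest falls among genes with adjusted p below 0.05, a mean log2 CPM of at least 2, groups that do not overlap and a symbol other than Gm with digits or ending in Rik, and from each list up to 4 members past the threshold with the largest change, or the 2 highest expressed where none passed. Some genes that the rule takes are not reported here. Any other list member named in the text was chosen after its values were seen.

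Replicates were compared before use. Between samples of a group the chi-square per degree of freedom over genes was 5.56 to 9.92, and between groups 303 to 338, so no pair agreed within sampling noise and each sample counted once. Of 126 named genes, 3 (Kif7, Nrarp and Ube2c) had over 20% of their exon length overlapping a gene on the opposite strand. Where a competent sample had 3 counts or fewer, the ratio of summed counts replaced the fitted fold change. This ratio was scaled by the TMM-adjusted library sizes and is given with a 95% exact interval. The edgeR and camera code was tested on simulated counts drawn from the means and library sizes of these samples. Of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, 34%, 86%, 100% and 100% were recovered among 13732 genes tested, and 0.12% of 13620 unchanged genes were called. A list shifted on purpose was called and 0 of 27 others were. Changes of 1.2-fold were thus missed more often than found in the simulation. Only 50 genes were changed at each fold and genes were drawn independently, whereas 69.2% of tested genes were called in the real comparison. The simulated shares of genes and lists called therefore check the code and do not carry over to the real data.

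Alternatives fixed beforehand were DESeq2-style and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 samples, the replicate number as a block, leaving out each sample in turn, an adjusted p below 0.01 and a fold change over 2. The median log2 change of all genes was -0.006 with TMM, -0.004 with DESeq2-style factors and -0.056 with upper-quartile factors. Further alternatives were chosen after the data were seen: removal of the trend with transcript length, by a loess curve per library used as an offset, and the list tests without immediate-early members.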

Results

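Messenger RNA was measured in 6 samples of mouse biliary epithelial cells, the cells that line the bile ducts. The bile ducts came from mouse liver and were expanded as organoids before the cells were moved to a flat culture on collagen. In 3 samples, called cilia competent, the cells had not received 4OHT. In the other 3, called cilia depleted, the cells had received it. 4OHT is the usual short form of 4-hydroxytamoxifen, a drug widely used to switch on a tamoxifen-dependent Cre recombinase and so delete a chosen gene. The primary cilium is a single sensory projection of the cell surface that in bile ducts reaches into the lumen. The deposited table gave whole-number counts for 32061 genes. Total counts were 32199606, 34153314 and 36093068 in the competent samples and 26293486, 33644130 and 36998935 in the depleted samples, and between 17004 and 17493 genes had at least 1 count in a sample. A floor of 3 counts corresponded to 0.0811 to 0.114 counts-per-million units (CPM), and such floors cover counting error only. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. 4OHT and cilium loss coincided in every sample and could not be separated.

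The comparison asked which genes differ in expression between cilia-competent and cilia-depleted biliary epithelial cells. Under the rule for named genes, immediate-early transcription factor genes rose most in the depleted cells, among them Fosb at 254-fold and Egr1 at 200.2-fold. NF-kB targets, senescence-associated secretory factors, p53 targets and genes of the unfolded protein and integrated stress responses stood above other genes as lists fixed beforehand, although none of these calls held with an estimated correlation between genes. The largest falls under the same rule were smaller, 5.43-fold at most, and included the mitochondrial mRNA mt-Nd3 and the surface antigen gene Ly6a. Genes outside that rule, such as those of low expression, were not ranked. Genes that build the cilium moved in both directions, by at most 3.25-fold among those listed. Of 13839 genes tested, 9576 (69.2%) changed at an adjusted p below 0.05, with 4832 higher and 4744 lower in the depleted cells. Most changes were small, since 5640 of these genes (58.9%) changed by less than 1.5-fold. Above 2-fold the balance was uneven, with 1021 genes higher and 345 lower, and above 4-fold 174 were higher and 16 lower. The 3 samples of the groups did not overlap at all for 10030 genes (72.5%), where chance gives 10%. The first principal component carried 83.9% of the variance and separated the groups.

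Wdr35, which encodes a component of the IFT-A complex of intraflagellar transport, was read first. The labels do not name the deleted gene; Wdr35 was chosen from knowledge of the study. Wdr35 (ENSMUSG00000066643; GRCm38 chromosome 12, 8973892 to 9028847, plus strand) had 33.3 ± 1.98 CPM in competent cells and 28.0 ± 1.6 CPM in depleted cells (SD, n = 3 each). Raw Wdr35 counts were 1211, 1148 and 1200 in the competent and 739, 914 and 925 in the depleted samples. Wdr35 expression was thus 1.19-fold lower, a log2 change of -0.25 (SE 0.062, adjusted p = 0.00245). A count over the whole gene does not resolve a deleted exon, so this value does not test whether the gene was disrupted or whether the group labels are right.

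Most of the 12 largest rises were immediate-early genes, which cells switch on within minutes of a stimulus without new protein synthesis. Fosb (chromosome 7, 19302696 to 19310051), an AP-1 subunit, rose from 6.94 ± 1.66 to 1754 ± 439 CPM (SD, n = 3; log2 change 7.99, SE 0.20, adjusted p = 1.35e-12). Egr1 (chromosome 18, 34859823 to 34864984), a zinc-finger transcription factor, rose from 41.1 ± 3.24 to 8226 ± 213 CPM (log2 change 7.65, SE 0.075, adjusted p = 6.05e-16). The related Egr2 rose 140-fold and Egr3 rose 99.6-fold. Egr4 had 6 counts over the competent samples and 1068 over the depleted samples. Scaled for library size, the ratio was 206 with a 95% counting interval of 94.2 to 562. Fos, the partner of Jun in AP-1, rose 32.5-fold, Atf3, a stress-induced repressor, rose 45.4-fold, and the orphan nuclear receptor Nr4a1 rose 22.1-fold. The others were Zfp36 (63.6-fold), which encodes an mRNA-destabilising protein, the interferon-inducible chemokine gene Cxcl10 (40.6-fold), the activity-regulated gene Arc (31.2-fold) and Csrnp1 (26.9-fold). The 10 most abundant genes took 7.06% to 7.25% of the counts in depleted samples and 5.13% to 5.35% in competent samples.

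Of the 12 largest falls, mt-Nd3, which encodes a subunit of respiratory complex I, fell most, from 240 ± 7.92 to 44.2 ± 6.11 CPM (SD, n = 3; 5.43-fold, adjusted p = 1.17e-11). Ly6a, which encodes the surface antigen Sca-1, was 4.81-fold lower, at 396 ± 24.7 against 82.4 ± 1.98 CPM. The protease inhibitor gene Serpinb1a (4.32-fold), Crip1 (4.31-fold), Tmem101 (4.30-fold) and the neutrophil chemokine gene Cxcl5 (4.05-fold) followed. Uts2b, Tmem50a and Skp1a were lower by 3.92-fold, 3.45-fold and 3.45-fold, with adjusted p of 2.46e-08, 7.92e-12 and 3.38e-11. Sprr2a1 and Sprr2a2 each fell 3.64-fold, but they are near-identical copies between which counting can split reads, so their separate values are uncertain.

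**Figure D1:**
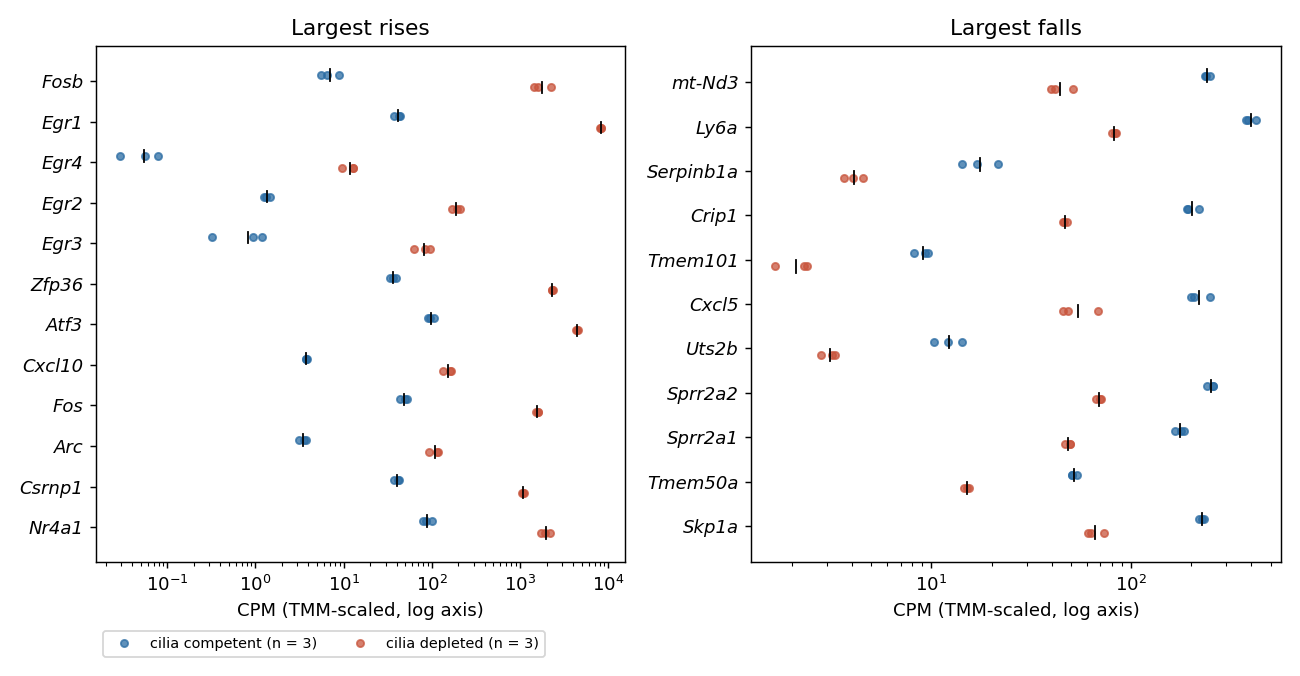
Expression of the 12 genes with the largest rise and 11 of the 12 with the largest fall under the rule for named genes. Values are CPM after scaling of the libraries, on log axes. Each point is a sample, the vertical tick is the mean of the 3 samples of a group, and the groups do not overlap for any gene shown; Egr1 lies near 41.1 CPM in competent and near 8226 CPM in depleted cells.

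The libraries differed by transcript length. Genes with short transcripts were lower in the depleted cells, with a median log2 change of -0.45 among protein-coding genes whose main transcript was 204 to 1291 nt long. Genes with long transcripts were higher, with a median of 0.28 among those of 6738 nt or more. Across 13831 genes, which are not independent replicates, Spearman's rho between transcript length and log2 change was 0.326, whereas rho with GC content was 0.00699. With the trend removed, a correction chosen after the data were seen, 9541 genes changed, and 8054 genes changed in the same direction with and without it.

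**Figure D2:**
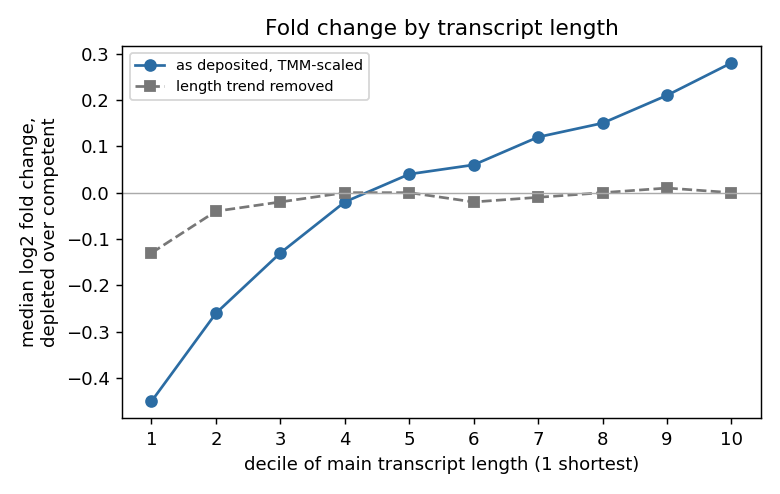
Median log2 fold change, depleted over competent, of protein-coding genes in 10 equal groups by length of the main transcript (group 1 shortest). The median runs from -0.45 to 0.28 in the counts as deposited and from -0.13 to 0 at the same ends once the length trend is removed.

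Of the 30 gene lists fixed before the data were examined, 28 were tested against all other genes. At an adjusted p below 0.05, 5 stood higher in depleted cells and 1 lower. With the correlation between genes estimated from the data, 0 of the 28 passed (camera), 5 had an unadjusted p below 0.05, and fry, which asks only whether members move on balance to the same side, called 20. Counts of members that rose or fell were identical when adjusted over the list alone, except where stated.

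Among the lists fixed beforehand, NF-kB targets and secreted factors had the highest medians. Of 16 NF-kB targets tested, 14 rose, 1 fell and 1 did not pass, with a median log2 change of 1.63 (adjusted p = 3.40e-17 for the list, adjusted p = 0.145 with an estimated correlation). Nfkbia, which encodes the inhibitor of NF-kB, rose 7.20-fold from 84.0 ± 3.71 to 605 ± 20 CPM (SD, n = 3). The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 rose 5.77-fold and 6.45-fold, while the adhesion molecule gene Vcam1 fell slightly (log2 change -0.19, adjusted p = 0.00447). Tnf counts were 7 over the competent and 53 over the depleted samples. Scaled for library size, the Tnf ratio was 8.75 with a 95% counting interval of 3.97 to 22.8. Of 30 senescence-associated secretory factors tested, 19 rose, 16 of them above 2-fold, 6 fell and 5 did not pass (median log2 change 1.12, adjusted p = 7.76e-11, adjusted p = 0.0723 with an estimated correlation). The stress cytokine gene Gdf15 rose 21.1-fold, from 35.8 ± 1.11 to 756 ± 32.4 CPM, and Csf2 rose 16.0-fold. The falls in this list included Cxcl5, Timp1 (log2 change -1.39) and Tgfb1 (log2 change -0.92). This list shared 7 members with other called lists, so the calls are not independent.

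Of 23 p53 targets tested, 14 rose, 7 fell and 2 did not pass (median log2 change 0.26, adjusted p = 3.20e-05, adjusted p = 0.0723 with an estimated correlation). The rise was largest for the antiproliferative gene Btg2 (17.9-fold), the pro-apoptotic Bbc3 (5.74-fold), Mdm2, which encodes the ubiquitin ligase of p53 (5.10-fold), and Plk2 (3.45-fold). Other targets fell, among them the pro-apoptotic Bax (log2 change -0.40) and Perp (log2 change -0.46). The list of cyclin-dependent kinase inhibitors, the usual markers of senescence arrest, divided. Of 7 tested, 2 rose, 2 fell and 3 did not pass, with a median log2 change of -0.04 and a list adjusted p of 0.976. Cdkn1a, which encodes p21, rose 1.69-fold from 214 ± 10.3 to 360 ± 6.46 CPM, and Cdkn2b, which encodes p15, rose 1.49-fold. Cdkn2a, which encodes p16 and p19Arf, fell 1.57-fold from 42.1 ± 2.71 to 26.9 ± 0.238 CPM (adjusted p = 2.54e-07). With the length trend removed, Cdkn2a was 1.25-fold lower. Cdkn2c fell 1.28-fold (adjusted p = 0.0241), a call lost with DESeq2 (adjusted p = 0.0670) and without competent replicate 2, competent replicate 3 or depleted replicate 3 (log2 changes -0.32, -0.34 and -0.25).

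Of 15 genes of the unfolded protein and integrated stress responses, 9 rose, 4 fell and 2 did not pass (median log2 change 0.34, adjusted p = 3.20e-05, adjusted p = 0.0723 with an estimated correlation). Atf3 led the list, followed by Ddit3, which encodes CHOP (7.05-fold, from 13.8 ± 1.66 to 97.0 ± 3.74 CPM), Dnajb9 (2.50-fold) and Chac1 (2.20-fold). The falling members were Creld2, Sdf2l1, Asns and Pdia4, with log2 changes between -0.71 and -0.32. Among 14 targets of the antioxidant factor NRF2, 3 rose, 10 fell and 1 did not pass, and the list as a whole did not pass (median log2 change -0.38, adjusted p = 0.574). Gstm1 fell 3.33-fold and Gsta4 3.11-fold, both encoding glutathione transferases, whereas Osgin1 rose 9.11-fold. The classical NRF2 target Nqo1 did not pass (log2 change -0.41, adjusted p = 0.153).

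Of 24 interferon-response genes, 11 rose, 2 fell and 11 did not pass, with a median log2 change of 0.17 and a list adjusted p of 0.240. The list passed, at 0.00535, when competent replicate 2 was left out. Cxcl10, Mx2 (8.55-fold, from 1.39 ± 0.625 to 11.8 ± 1.2 CPM) and Stat2 (2.54-fold) rose, whereas Gbp2 and Bst2 fell (log2 changes -0.71 and -0.70). Isg15 and Ifit3, standard markers of interferon signalling, did not pass (adjusted p = 0.0946 and 0.140).

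A pair of lists addressed what 4OHT itself can do. Of 7 oestrogen-responsive genes tested, 2 rose (Fos and Areg, at 32.5-fold and 2.47-fold), Ctsd fell 1.44-fold and 4 did not pass. The list passed with a median log2 change of 0.36 (adjusted p = 0.0206, adjusted p = 0.255 with an estimated correlation), but not without Fos (adjusted p = 0.946) or without competent replicate 2 (adjusted p = 0.0506). Fos also belongs to the immediate-early genes. Of 19 cholesterol synthesis genes, 8 rose, 5 fell and 6 did not pass (median log2 change 0.11, adjusted p = 0.999). Insig1, which encodes a brake on sterol regulatory element-binding proteins, rose 3.39-fold, while Nsdhl fell 1.57-fold.

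Ciliary machinery moved in both directions and no ciliary list passed. Of 18 IFT-B genes, whose products carry cargo towards the ciliary tip, 5 rose, 11 fell and 2 did not pass (median log2 change -0.23, adjusted p = 0.574). Ift20 was 1.93-fold lower, at 23.1 ± 0.562 against 12 ± 0.578 CPM (SD, n = 3; adjusted p = 2.81e-08), and Ift27 was 1.83-fold lower. Ttc30a1 was 1.96-fold lower, but it has close copies in Ttc30a2 and Ttc30b that can share reads. Ift81, Ift88, Ift172, Cluap1 and Ift46 rose, with log2 changes of 0.13 to 0.45. Of 7 IFT-A genes, 3 rose (Ift140 1.29-fold, Ift122 1.2-fold and Tulp3, log2 change 0.17) and 2 fell (Ift43 1.41-fold and Wdr35). The IFT-A median log2 change was 0.11 (adjusted p = 0.999), and -0.11 with the length trend removed. Of 9 genes of the BBSome and its recruiter, 2 rose (Bbs4 and Bbs2), 2 fell (Bbip1 1.55-fold and Arl6 1.51-fold) and 5 did not pass (adjusted p = 0.909). Their median log2 change was 0.03, and -0.02 with upper-quartile scaling. Of 19 transition zone and ciliary membrane genes, 11 rose, 6 fell and 2 did not pass (median log2 change 0.22, adjusted p = 0.841). Tmem216 fell 3.25-fold, from 15.1 ± 0.5 to 4.67 ± 0.595 CPM, while Cc2d2a rose 1.97-fold, Cep290 1.75-fold and Nphp4 1.64-fold. Pkhd1, which encodes fibrocystin, rose (log2 change 0.65), Pkd2, which encodes polycystin-2, fell (log2 change -0.42), and Pkd1 did not pass (adjusted p = 0.170). Within these lists log2 change was higher for longer transcripts, with Spearman's rho across members of 0.62 for the transition zone list and 0.21 for the IFT-B list. With the length trend removed Tmem216 remained lower (log2 change -1.38) and Cep290 higher (0.53), and Ift20 moved from -0.95 to -0.64. Of 6 tested genes of motile cilia, Foxj1, the transcription factor that drives their formation, rose 1.63-fold from 183 ± 11.6 to 297 ± 8.58 CPM, Ccdc39 rose 2.01-fold, Rsph1 fell 1.74-fold and 3 did not pass (median log2 change 0.44, adjusted p = 0.695).

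Signalling lists that depend on or interact with cilia did not pass as lists, while several of their members changed above 2-fold. Of 8 Hedgehog pathway genes, 6 rose, 1 fell and 1 did not pass, and 7 rose and 1 fell when adjusted over the list alone (median log2 change 0.57, adjusted p = 0.643). Gli3, a transcription factor of the pathway, rose 1.77-fold, the receptor gene Ptch1 rose (log2 change 0.28) and Smo fell (log2 change -0.28). Kif7 rose 1.62-fold, although its exons overlap a gene on the opposite strand and the strand setting of the counting was not given. Of 9 canonical Wnt targets, 3 rose, 4 fell and 2 did not pass (median log2 change 0.41, adjusted p = 0.695). Myc rose 3.22-fold from 145 ± 4.53 to 466 ± 11.5 CPM, and the Wnt receptor ligases Rnf43 and Znrf3 rose (log2 changes 0.95 and 0.94). Tcf7, Axin2 and Sp5, commonly used readouts of the pathway, fell 2.12-fold, 2.05-fold and 2.01-fold, and Ccnd1 fell slightly. Of 10 Notch pathway genes, 3 rose, 3 fell and 4 did not pass (median log2 change 0.14, adjusted p = 0.643). Hes1 rose 4.17-fold from 51.2 ± 1.55 to 213 ± 21.6 CPM, and the receptor genes Notch1 and Notch2 rose 1.88-fold and 1.61-fold, while Nrarp, which also overlaps an opposite-strand gene, and the ligand genes Jag1 and Jag2 fell. Of 22 YAP/TAZ targets, 11 rose, 8 fell and 3 did not pass (median log2 change 0.10, adjusted p = 0.240, and median -0.17 with the length trend removed). Gadd45a rose 3.97-fold, Ccn1 3.84-fold and Ankrd1 2.54-fold, and Igfbp3 and Fjx1 fell (log2 changes -0.74 and -0.95).

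Cell cycle genes changed modestly and without a common direction. Of 25 DNA replication genes, 6 rose, 13 fell and 6 did not pass (median log2 change -0.13, adjusted p = 0.680). Ccne1, which encodes cyclin E1, fell 2.23-fold from 6.33 ± 0.377 to 2.81 ± 0.471 CPM, and Rrm2, a subunit gene of ribonucleotide reductase, fell 1.82-fold, while the licensing factor gene Cdt1 rose 1.59-fold. Of 21 mitosis genes, 7 rose, 8 fell and 6 did not pass. The mitosis median log2 change was 0.04 and the mean 0.03, but the list test pointed down (adjusted p = 0.957) and the median was -0.01 with upper-quartile scaling. Mki67, the proliferation marker, rose 1.73-fold from 68.4 ± 11.4 to 118 ± 7.33 CPM and Cenpe 1.64-fold, both from long transcripts, whereas Ccnb2 fell 1.41-fold. With the length trend removed, 5 mitosis genes rose, 4 fell and 12 did not pass, with a median of -0.02, and the rise of Mki67 moved from 0.79 to 0.48 on the log2 scale. Of 15 DNA repair genes, 9 rose, 2 fell and 4 did not pass (median log2 change 0.27, adjusted p = 0.680). Brca2 rose 2.20-fold and Xrcc2 1.72-fold, and H2afx fell (log2 change -0.46). With the length trend removed, 5 repair genes rose, 3 fell and 7 did not pass.

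Biliary identity genes moved in both directions. Of 19 tested, 7 rose, 9 fell and 3 did not pass. The median log2 change was -0.19 and the mean 0.07, and the list did not pass (adjusted p = 0.976, pointing up). The transcription factor genes Sox9 (3.98-fold, from 88.2 ± 0.774 to 351 ± 17.9 CPM), Onecut1 (2.67-fold) and Foxa2 (2.13-fold) rose, as did the claudin gene Cldn4 (2.14-fold). Spp1, which encodes osteopontin, Epcam and Cd24a fell, with log2 changes of -0.97, -0.90 and -1.02, and Krt7 and Krt19 fell with log2 changes of -0.35 and -0.57. Krt7 was at 3150 ± 67.7 CPM in competent cells and Krt19 at 12.5 ± 1.13 CPM. Of 18 tight junction and polarity genes, 7 rose, 8 fell and 3 did not pass (median log2 change -0.05, adjusted p = 0.776). Cldn2, which encodes a pore-forming claudin, fell 3.17-fold from 147 ± 8.89 to 46.3 ± 0.665 CPM and Ocln, which encodes occludin, fell 1.95-fold, whereas Pard6b rose 1.85-fold.

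Of 23 genes of the extracellular matrix and mesenchymal transition, 9 rose, 6 fell and 8 did not pass, with 9 and 7 when adjusted over the list alone (median log2 change 0.09, adjusted p = 0.695, and median -0.04 with the length trend removed). Thbs1, which encodes thrombospondin 1, and Zeb1 rose (log2 changes 1.08 and 0.82). Snai1 rose 2.40-fold and Col1a1 2.18-fold from low levels of 0.642 and 1.38 CPM, and Acta2, the smooth muscle actin gene, fell 3.8-fold from 1.29 CPM. Markers of other liver cells stayed low or mixed. Of 12 mesenchymal markers listed, 3 could be tested: Col1a1 rose, Acta2 fell and Reln did not pass. Their median log2 change was 0.26, the mean -0.18 and the list adjusted p = 0.999, and the median was -0.07 with the length trend removed. Of 11 leukocyte markers, 3 could be tested: Cd68 rose 1.57-fold, Cd14 rose 1.22-fold from 233 ± 11.1 CPM, and Csf1r fell 1.09-fold (adjusted p = 0.0496, list adjusted p = 0.906), a call that was lost with DESeq2 (adjusted p = 0.0971). Of 9 endothelial markers, only Vwf could be tested, at 0.340 and 0.379 CPM (adjusted p = 0.829). Among 7 tested hepatocyte markers, Apob (2.10-fold) and Hnf4a (log2 change 0.16) rose, Fgb, Ttr and Ass1 fell, though Ttr did not pass with the length trend removed (adjusted p = 0.118), and Alb, which encodes albumin, stayed at 2.61 and 2.57 CPM (adjusted p = 0.936 for the gene, 0.940 for the list).

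Of 13 mitochondrially encoded mRNAs, 1 rose (mt-Co1, log2 change 0.29), 8 fell and 4 did not pass (median log2 change -0.79, adjusted p = 0.00727, adjusted p = 0.969 with an estimated correlation). After mt-Nd3, the largest falls were those of mt-Cytb (2.19-fold), mt-Co3 (2.00-fold) and mt-Atp8 (1.87-fold). Once the length trend was removed the list did not pass (adjusted p = 0.128), with a median log2 change of -0.44, 4 members higher, 8 lower and 1 that did not pass. Without the trend mt-Nd3 was still lower, with a log2 change of -2.08 (SE 0.056) against -2.44 (SE 0.076) with it. These mRNAs took 1.78%, 2.16% and 2.04% of counts in the competent and 1.25%, 1.52% and 1.65% in the depleted samples. Sex-linked genes were read as a check on the samples. Xist had 0 to 4 counts in a sample, while 4 Y-linked genes were expressed in all 6 samples. Of these, Uty, Kdm5d and Ddx3y rose by 1.57-fold, 1.15-fold and 1.09-fold and Eif2s3y did not pass (adjusted p = 0.0566), and adjusted over the list alone Eif2s3y fell. With the length trend removed the log2 changes of Kdm5d and Ddx3y were -0.06 and -0.03 and did not pass.

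**Figure D3:**
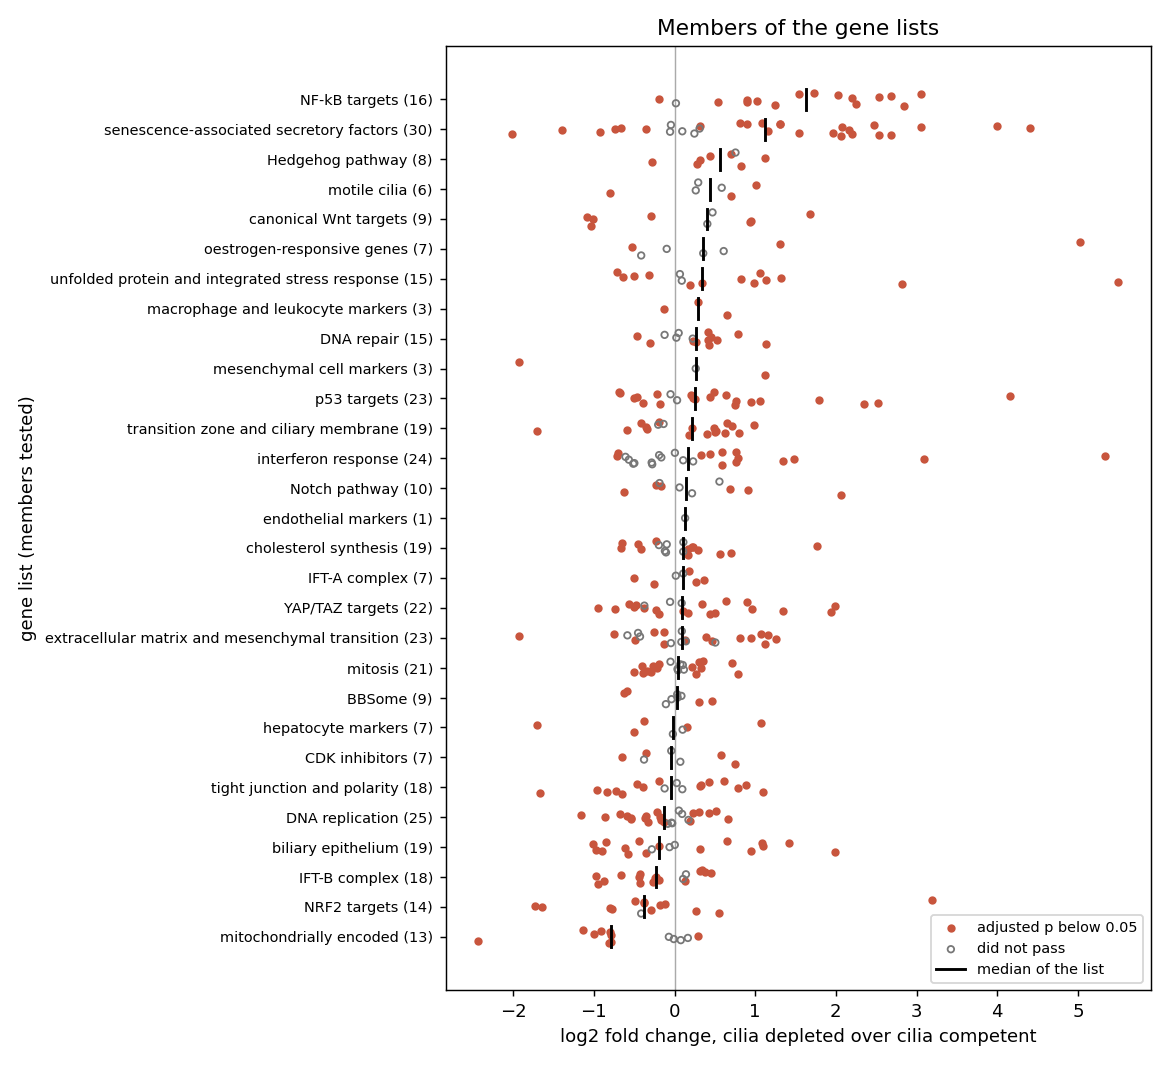
Log2 fold change, depleted over competent, of each tested member of the 29 gene lists other than the sex-linked check, with the number of members tested in brackets. Filled points passed an adjusted p of 0.05 in the gene test and open points did not; the vertical bar is the list median, from 1.63 for NF-kB targets to -0.79 for mitochondrially encoded mRNAs.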

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

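The length-trend removal and the list tests without immediate-early members were chosen after the data were seen; the other settings were planned. The 9576 changed genes became 8929 to 9333 when single samples were left out, 8317 at an adjusted p below 0.01, 8943 with DESeq2, 9759 without a filter, 9541 with the length trend removed and 1366 (1021 higher, 345 lower) with a fold change over 2, where the added condition itself removes genes. With the replicate number as a block the count was 9526, 6 lists were called and no named gene changed its call. No pairing by replicate number was seen. Samples sharing a number deviated from their group means with correlations of -0.028, 0.013 and -0.016. No sample correlated best with the sample sharing its number. The labels do not say whether the numbers mark a shared culture, and these correlations cannot exclude it. Upper-quartile factors gave 4434 higher and 5236 lower genes, against 4832 and 4744. Wdr35 kept its direction and passed in every setting, between -0.29 and -0.21 on the log2 scale with single samples left out and at -0.40 with the length trend removed (adjusted p between 2.31e-05 and 0.0146 over the alternatives). Of 28 lists, 6 were called with every single sample left out, but without competent replicate 2 the oestrogen-responsive list was lost (adjusted p = 0.0506) and the interferon list gained (0.00535). Camera with an estimated correlation called 0 lists (5 at an unadjusted p below 0.05) and fry called 20, 16 up and 4 down; fry does not compare a list with other genes, and the cause of the loss under an estimated correlation was not tested. Removing the length trend left 5 lists called, without the mitochondrially encoded mRNAs (adjusted p = 0.128, range over the alternatives 0.00011 to 0.969). Leaving out immediate-early members also left 5, without the oestrogen-responsive genes (0.946, range with camera 0.0016 to 0.946). Of 125 named genes other than Wdr35 (119 of them tested with the filter of 1 CPM), at most 5 lost their call under another scaling, test, filter or block or with a single sample left out; the stricter thresholds were applied to the count of genes only. Kdm5d and Ddx3y reversed with the length trend removed, to -0.06 and -0.03; the cause for these genes was not tested further. Kdm5d also lost its call without competent replicate 1 (0.18), depleted replicate 2 (0.18) or depleted replicate 3 (0.17), and Ddx3y without competent replicate 1 (0.12), competent replicate 3 (0.11) or depleted replicate 3 (0.10). Csf1r lost its call without competent replicate 1, 2 or 3 (-0.12, -0.14 and -0.13) or depleted replicate 2 (-0.07), and Cdkn2c without competent replicate 2 or 3 (-0.32 and -0.34) or depleted replicate 3 (-0.25). Depth limits genes near the floor of 3 counts, such as Egr4 and Tnf in competent samples.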

Other observations

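All tests and gene lists in this part were chosen after the results were seen. Of 40 immediate-early genes tested, 39 rose, 35 of them above 2-fold, and Klf2 did not pass (log2 change 0.14, adjusted p = 0.0918). The median log2 change was 3.17, and the list passed with an estimated correlation (adjusted p = 0.00288), though its members were chosen after the largest rises were known. Beyond the genes already described, Dusp1, which encodes a MAP kinase phosphatase, rose 15.4-fold, Jun 14.9-fold and Ier2 12.3-fold. Of 13 feedback genes of the ERK pathway, 9 rose, 3 fell and Etv1 did not pass (median log2 change 1.79, adjusted p = 0.00288 with an estimated correlation). Errfi1, a feedback inhibitor gene of the EGF receptor, rose 9.38-fold, Dusp5 8.78-fold, Spry2 6.07-fold and Dusp6 5.80-fold, whereas Etv4, Etv5 and Spred1 fell (log2 changes -0.64, -0.62 and -0.31).

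Clock genes were also higher. Of 17 tested, 15 rose and Cry1 and Clock did not pass (median log2 change 0.86, adjusted p = 0.00377 with an estimated correlation). Nr1d1, which encodes the repressor REV-ERB alpha, rose 19.1-fold from 32.8 ± 2.28 CPM, Per1 rose 11.1-fold, Bhlhe40 8.01-fold and Nfil3 6.94-fold, and Per1 also stands among the immediate-early genes. Of 12 heat shock genes, 9 rose and 3 fell (median log2 change 0.44, adjusted p = 0.284 with an estimated correlation). The near-identical copies Hspa1a and Hspa1b rose 9.43-fold and 8.18-fold, and the mitochondrial chaperone genes Hspd1 and Hspe1 fell, as did Dnaja1 (log2 changes -0.28, -0.18 and -0.19). Of 57 cytosolic ribosomal protein genes, 1 rose (Rpl3), 22 fell and 34 did not pass. Their median log2 change was -0.10 (adjusted p = 0.0951, adjusted p = 0.77 with an estimated correlation), and it turned to 0.23 with the length trend removed (adjusted p = 0.00301).

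The number of changed genes was high for 3 samples against 3. Counting the 10 ways to split the 6 libraries into equal groups, 1 split, the real one, gave 9576 genes, and the highest other count was 0 (edgeR; at most 136 genes at an unadjusted p below 0.05 in another split). With 10 splits the share cannot fall under 0.05. Every other split also placed competent and depleted libraries together in each group, which widens the spread within it. Low counts there were foreseeable and do not test chance. Libraries of a group differed by a chi-square per degree of freedom of at least 5.56, which argues against a single library sequenced repeatedly. Whether the 3 samples of a group were wells of a single culture stays open, as does the difference between cilium loss and 4OHT treatment, which was not tested because they coincide in all samples.

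Short transcripts were lower and long transcripts higher in the depleted libraries, and each of the 6 libraries followed its group (rho with length of -0.386 to -0.27 in competent and 0.275 to 0.34 in depleted). Long genes induced above 1.5-fold do not account for all of this, since rho was still 0.259 across the 9698 genes that changed by less than 1.5-fold. Smaller regulated changes that follow length are not excluded, since 5640 genes passed the adjusted p threshold with changes under 1.5-fold. Ribosomal protein genes lay 0.40 above genes of matched length in log2 change (95% bootstrap interval 0.28 to 0.45), so length alone did not set their change. This cannot decide whether other short transcripts were lost by length alone. Ribosomal protein genes are a single functional group that may shift together, and the interval treats them as independent. A difference in how libraries recovered transcripts by length stays a candidate explanation: across 11 mature mitochondrial mRNAs rho was 0.555 (permutation p = 0.0829) and Pearson's r 0.728 (permutation p = 0.0104), but without the 2 farthest from the median length they were 0.233 and 0.618 (permutation p = 0.552 and 0.0788), so the relation rests on those mRNAs. It cannot be told apart from a change in the cells, since library and group coincide.

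The rise of immediate-early genes may reflect a stimulus in the depleted cultures or a response of the cells to cilium loss. The length trend is argued against, since 100% of the 35 genes above 2-fold stayed above it once the trend was removed. A stimulus or handling difference shortly before lysis cannot be told apart from the group, because it would coincide with it in every library. Heat shock genes had a median log2 change of 0.44, and members moved in both directions. Of 12 tested, 9 rose, Hspa1a by 9.43-fold and Dnajb1 by 4.35-fold, and 3 fell, by 1.21-fold at most. A response to 4OHT itself cannot be told apart either: the 6 oestrogen-responsive genes outside the immediate-early list had a median log2 change of 0.13, with Areg higher and Ctsd lower. An effect of cilium loss stays open and was not tested.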
